A study of Homo sapiens with 6 samples.

How the data were processed

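Poly(A) RNA of U2OS cells was sequenced in 6 libraries, 3 of wild-type (WT) cells and 3 of a single clone, G3C2, labelled deficient in ZFP36L1 after CRISPR/Cas9 editing. Groups and replicate labels (1, b and c) were taken from the sample titles. The series text gives 3 WT and 3 deficient samples grown on 3 occasions. The sample titles do not say which occasion each library came from. The p-values measure the spread between these libraries, part of which may be technical. With 1 clone, the effects of the genotype and of the clone cannot be told apart.

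Gene values were deposited as FPKM in 2 tables, per the file headers, the first with replicate 1 and the second with replicates b and c. The submitters' processing notes name CASAVA, HISAT2 and the build GRCh38.p12, and no versions. Counting and strand settings were not given in the sources used here. The first table listed 60448 identifiers, the second 59108, and 56982 were in both, of which 56868 matched a GENCODE 29 gene. The tables had separate scales. Summed FPKM was 705014 and 712633 in the first table and between 235190 and 319282 in the second, so each genotype difference was taken within a table.

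FPKM are not counts, but the steps between low values carry the depth. With exon lengths from GENCODE 29, between 97.3% and 97.4% of the second table's values in each library were whole reads within a tolerance of 0.02 reads. The recovered reads, rounded, came to 28980000 for WT replicate b, 22610000 for WT replicate c, 26100000 for deficient replicate b and 25840000 for deficient replicate c. The divisor behind the deposited FPKM was not these totals. It lay between 22560000 and 29670000 reads, close to library sizes scaled by median-of-ratios factors (22660000 to 29730000). In the first table between 34.6% and 36.1% of values came out whole with these lengths, and its depth was not recovered.

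The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a term for genotype and a term for table, a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. Genes needed an FPKM of at least 1 in at least 2 libraries and a value in both tables, which left 15001. Fold changes on this scale understate the change of genes with low values. Tested on simulated data for this comparison over 15001 genes, the fit recovered 11 of 50 genes changed 2-fold, 43 of 50 changed 4-fold, 50 of 50 changed 8-fold and 45 of 50 changed 16-fold, with 7 false calls. The simulated noise was independent between genes and between libraries, and the changes were added on the log2(FPKM + 1) scale. Recovery and false calls in the real libraries may therefore differ.

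Same-numbered libraries deviated together from their group means across genes (r = 0.93, 0.80 and 0.60 for replicates 1, b and c), which pairs them by the rule used, although the separate tables alone produce such a pattern. Within the second table r was -0.17. A fit with the replicate label as a block was run beside the main one.

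A set of 30 gene lists with 901 genes was fixed before the data were examined, and 28 lists had at least 5 tested genes. Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The genes named were fixed by a rule before the data were examined. They were ZFP36L1, ZFP36 and ZFP36L2, then up to 12 protein-coding genes with the largest rise and 12 with the largest fall past the adjusted threshold, in the same direction in all 3 replicate pairs and with a mean FPKM of at least 1 in the higher group in each table. For each list, up to 4 members past the threshold were named or, where none passed, up to 2 with the largest mean FPKM, as values. Other genes were chosen after their values were seen. They include the members named for passing an adjustment over their list alone, which does not correct for the number of lists.

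Alternatives were a pseudocount of 0.1, other filters, the block, no table term, the second table alone, other scalings and variance models, and each library and each replicate pair left out. Chosen after the data were seen were a crossed block, limma-voom on the recovered reads of the second table, and the removal of genes near 0 in 1 table and abundant in the other. AU-rich elements were searched as TATTTAT in the longest annotated 3′ untranslated region of 19569 genes. Further steps used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Some further results are not reported here.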

Results

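The data were gene expression values of U2OS cells, a human osteosarcoma line, grown to 65 to 75% confluency. Of the 6 poly(A) RNA libraries, 3 were from WT cells and 3 from the clone G3C2, labelled deficient in ZFP36L1, an RNA-binding protein that recognises AU-rich elements in 3′ untranslated regions and recruits the machinery that removes poly(A) tails. Each genotype had a replicate labelled 1, b and c. Replicate 1 stood in a first FPKM table and replicates b and c in a second, which held between 22610000 and 28980000 recovered reads per library.

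ZFP36L1 mRNA was not lower throughout in the clone labelled deficient. ZFP36L1 (ENSG00000185650, chromosome 14, 68787660 to 68796253 on the minus strand, GRCh38) had FPKM of 165.2 in WT and 238.1 in the clone for replicate 1, 57.1 and 105.1 for replicate b, and 127.5 and 82.4 for replicate c. Its log2 fold change, clone minus WT, was 0.26 (SE 0.33, n = 3 per genotype, limma adjusted p = 0.752). It was higher in the clone in 2 of 3 pairs, and without replicate c it passed the threshold (0.70, limma adjusted p = 0.0237). Without replicate b it was -0.05, without WT replicate b -0.03, with limma-voom on the recovered reads -0.073 and with quantile normalization 0.03, with adjusted p between 0.971 and 0.992. The position of the edit was not given in the sources used here, and an edit can remove a protein without lowering its mRNA, so the transcript level does not check the genotype. The paralog ZFP36L2 had a log2 fold change of 0.56 (SE 0.18) and ZFP36 of -0.58 (SE 0.24), with limma adjusted p of 0.261 and 0.365.

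The comparison of the genotypes asks which transcripts differ in cells labelled as lacking ZFP36L1. KLK6, a secreted serine protease, fell by 3.81 on the log2 scale (SE 0.19), from 14.96, 20.2 and 29.9 FPKM in WT replicates 1, b and c to 0.26, 0.82 and 0.65 in the clone. CDA, the cytidine deaminase of pyrimidine salvage, fell by 2.48 (SE 0.17), COL22A1, a collagen chain, by 2.18 (SE 0.17), and BCHE, butyrylcholinesterase, by 1.87 (SE 0.15). GTSF1, a small RNA pathway protein of germ cells, rose by 3.99 (SE 0.28), from 3.79, 0.91 and 0 FPKM in WT to 71.7, 17.6 and 26.1 in the clone. NUDT14, a UDP-sugar pyrophosphatase, rose by 2.14 (SE 0.18), from between 1.89 and 3.11 FPKM in WT to between 12.7 and 15.7 in the clone.

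These were the protein-coding genes among the 3 higher and 4 lower of 15001 tested (limma adjusted p between 0.00911 and 0.0417), each in the same direction in 3 of 3 pairs. The remaining gene, named after its values were seen, was the antisense gene AC004884.2 (log2 fold change 1.80, SE 0.14), whose reads cannot be told from those of an overlapping gene without strand. At an unadjusted p under 0.05, 928 genes were higher and 1115 lower, where chance gives 750 in all. KLK6 (chromosome 19) and CDA (chromosome 1) had limma adjusted p of 0.00911 and 0.0287, GTSF1 (chromosome 12, 54455950 to 54473602) 0.0287, COL22A1 (chromosome 8) and BCHE (chromosome 3) 0.0308, and NUDT14 (chromosome 14, 105172938 to 105181323) 0.0417. With the replicate block, KLK6 alone passed (limma adjusted p = 0.0474), and the other 6 had adjusted p between 0.0783 and 0.1. With a pseudocount of 0.1, GTSF1 (limma adjusted p = 0.122) and NUDT14 (0.0517) did not pass, nor did NUDT14 with quantile normalization (0.0612). Without replicate 1 no gene passed (1110 at an unadjusted p under 0.05), and without replicate c, with 1 residual degree of freedom, 448 were higher and 457 lower.

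**Figure D1:**
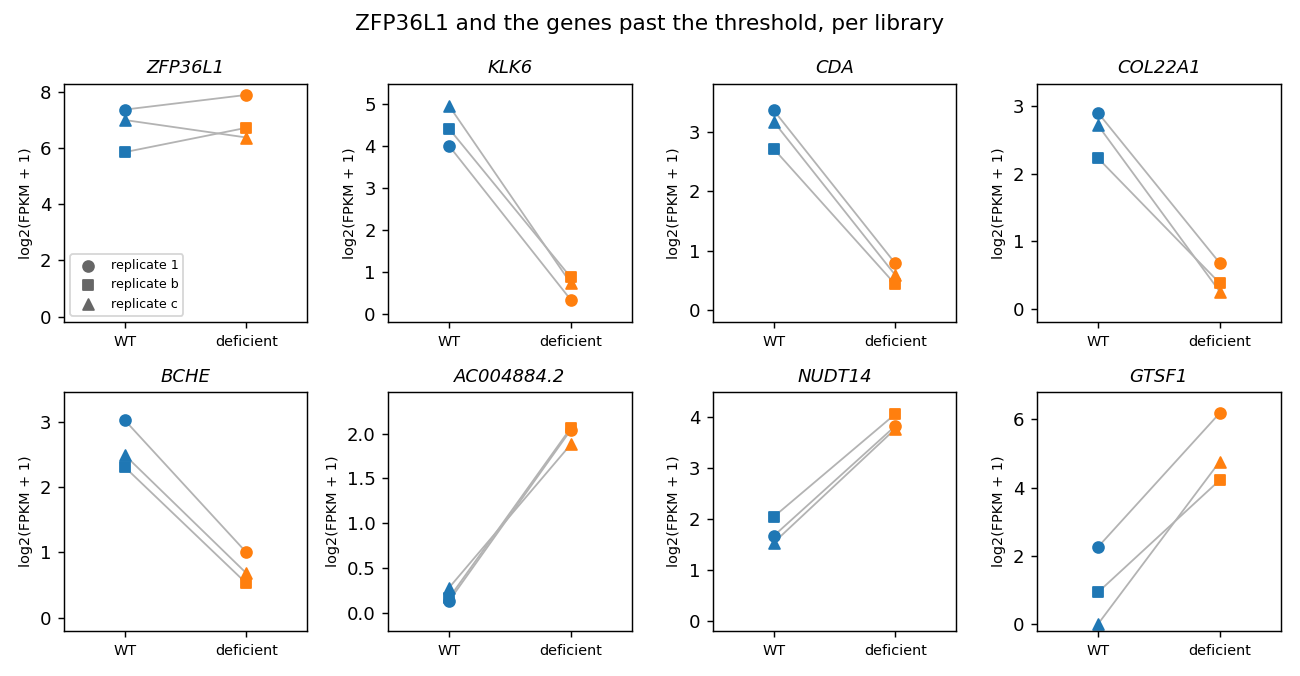
Log2(FPKM + 1) of ZFP36L1 and of the 7 genes past the threshold, with a panel for each gene, WT in blue and the clone labelled deficient in orange, a marker shape for each replicate label and grey lines joining the pairs. GTSF1, NUDT14 and AC004884.2 were higher in the clone in all 3 pairs, KLK6, CDA, COL22A1 and BCHE lower, and ZFP36L1 went both ways.

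Genes of cholesterol synthesis and genes induced by interferon lay lower in the clone in every replicate pair, as sets. The cholesterol list had medians of -0.51, -0.27 and -0.49 for replicates 1, b and c, with 19 of 27 tested members lower in all 3 pairs. The interferon list had medians of -0.31, -0.16 and -0.57, with 18 of 34 lower in all 3. Both had a limma camera adjusted p of 5.59e-06 against the other genes, and an adjusted p of 0.829 with an estimated correlation. No member passed over all genes. Adjusted over the list alone, MVK (log2 fold change -0.76) and MVD (-1.18), enzymes of the mevalonate pathway, passed in the cholesterol list, and OAS3 (-0.84) and IFIH1 (-1.14), sensors of viral RNA, in the interferon list. The most abundant cholesterol list members, SCD and FASN, had -0.55 (SE 0.37) and -0.49 (SE 0.26), and B2M and IFITM3 of the interferon list -0.17 (SE 0.19) and 0.02 (SE 0.20).

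Cytosolic ribosomal proteins, mitosis and DNA replication genes were higher as sets, with medians above 1 in replicate c alone. The ribosomal list had medians of 0.23, -0.04 and 1.16 (limma camera adjusted p = 6.47e-08), the mitosis list 0.06, -0.31 and 1.06 (0.00149) and the replication list -0.14, -0.18 and 1.06 (0.00264). All 3 had an adjusted p of 0.829 with an estimated correlation. From replicate b to c the ribosomal list moved by a median of -0.64 in WT and 0.56 in the clone. The mitosis list moved by -0.64 in WT and 0.73 in the clone, and the replication list by -0.67 and 0.57. The medians per pair of these 3 lists therefore depend on the pairing by label. Without replicate c the ribosomal list was still higher (limma camera adjusted p = 0.00822), the replication list was lower (0.0226) and the mitosis list did not pass (0.194). RPLP0, a protein of the large ribosomal subunit, had 592 and 522 FPKM in WT and clone replicate b and 368 and 811 in replicate c, and CCNB1, cyclin B1, 167 and 134 in replicate b and 95.4 and 246 in replicate c. None of the 68, 42 and 51 tested members passed over all genes or adjusted over the list alone. In WT replicate c, all genes of the mitochondrial genome, not its mRNAs alone, took 13.8% of the summed FPKM. The share was 8.7% in WT replicate b and 7.4% and 6.7% in the clone's replicates b and c.

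Of the other lists, the Wnt list was higher (limma camera adjusted p = 0.00038, medians 0.48, 0.43 and 0.01), with WNT5A (1.19, SE 0.19) past the threshold adjusted over the list alone. Replication-dependent histones, whose main transcripts lack poly(A) tails, were lower as a set (0.00038, medians -0.40, -0.07 and -1.03), with 7 of 13 lower adjusted over the list alone, among them H2BC12 (-0.82, SE 0.28). Immediate-early genes (0.0103, medians 0.00, -0.57 and -0.27), mitochondrial mRNAs (0.0377, medians -0.09, -0.36 and -0.49) and 5 neural markers (0.0447, medians 0.06, -0.15 and -0.74) were lower by the same test. Cancer-testis antigens were higher (0.0358, medians -0.04, 0.03 and 0.84). With the replicate block, mitochondrial mRNAs (limma camera adjusted p = 0.118) and cancer-testis antigens (0.0504) did not pass. Without replicate c the histone (0.195), mitochondrial (0.305), neural (0.542) and cancer-testis (0.627) lists did not pass. The 11 lists past the threshold all had an adjusted p of 0.829 with an estimated correlation. By limma's fry, apoptosis regulators passed for movement in 1 direction, down (adjusted p = 0.0165), with a mean log2 fold change of -0.13 and a median of 0.01. For change in either direction, 7 lists passed fry, among them the deadenylation and decay machinery (adjusted p = 0.00856), osteoblast markers (0.00856), NF-kB targets (0.00919) and matrix genes (0.0103). Fry asks whether a list changed at all, not whether it changed more than other genes. Over all 15001 tested genes, 2043 had an unadjusted limma p under 0.05.

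By the label pairing, genes of the extracellular matrix and of adhesion lay higher in replicates 1 and b and lower in replicate c. The list of fibrillar and basement membrane matrix had medians of 0.35, 0.33 and -0.53 for replicates 1, b and c, and was not called over all 3 pairs (limma camera adjusted p = 0.99). From replicate b to c this list moved by a median of 0.23 in WT and -0.45 in the clone. Its reversal between these pairs therefore depends on the pairing by label. Members that passed adjusted over the list alone included THBS1 (log2 fold change 1.90) and PLOD2 (0.86), which were higher, and the laminin chain LAMB3 (-2.41) and the collagen chain COL16A1 (-1.13), which were lower. The same adjustment passed TNFAIP2 (2.87) in the NF-kB list, BMP4 (1.25) in the osteoblast and TGF-beta lists, AKT1 (0.94) and EGFR (-1.02) in the list of receptor tyrosine kinases and AKT signalling, and MAP2 (-1.58) among the neural markers. Without replicate c, with 1 residual degree of freedom, the matrix list was higher (limma camera adjusted p = 8.25e-06 at the preset correlation). So were the lists of integrins and adhesion (0.00139), osteoblast markers (0.00325), TGF-beta targets (0.00528) and matrix proteases (0.00822). An estimated correlation, used over all 3 pairs only, gave camera adjusted p of 0.997 for the matrix list and 0.829 for each of the others. COL1A1, a chain of type I collagen, had 209 and 899 FPKM in WT and clone replicate 1, 82.1 and 248 in replicate b and 184 and 192 in replicate c.

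Transcripts reported as targets of the ZFP36 family were not called higher or lower as a set. Of 37 tested, none passed over all genes or adjusted over the list alone. The median log2 fold change was -0.10 (limma camera adjusted p = 0.876), with 10 members higher and 11 lower in all 3 pairs. CCND1 had a log2 fold change of 0.47 (SE 0.18) and HIF1A 0.35 (SE 0.16). The list of AU-rich element binding proteins includes ZFP36, ZFP36L1 and ZFP36L2. That list (15 tested, median 0.10, adjusted p = 0.7) and the deadenylation and decay machinery (27 tested, median 0.03, adjusted p = 0.363) did not pass camera either. Of the genes called, none of the 2 higher and 4 lower with a searched 3′ untranslated region held TATTTAT.

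**Figure D2:**
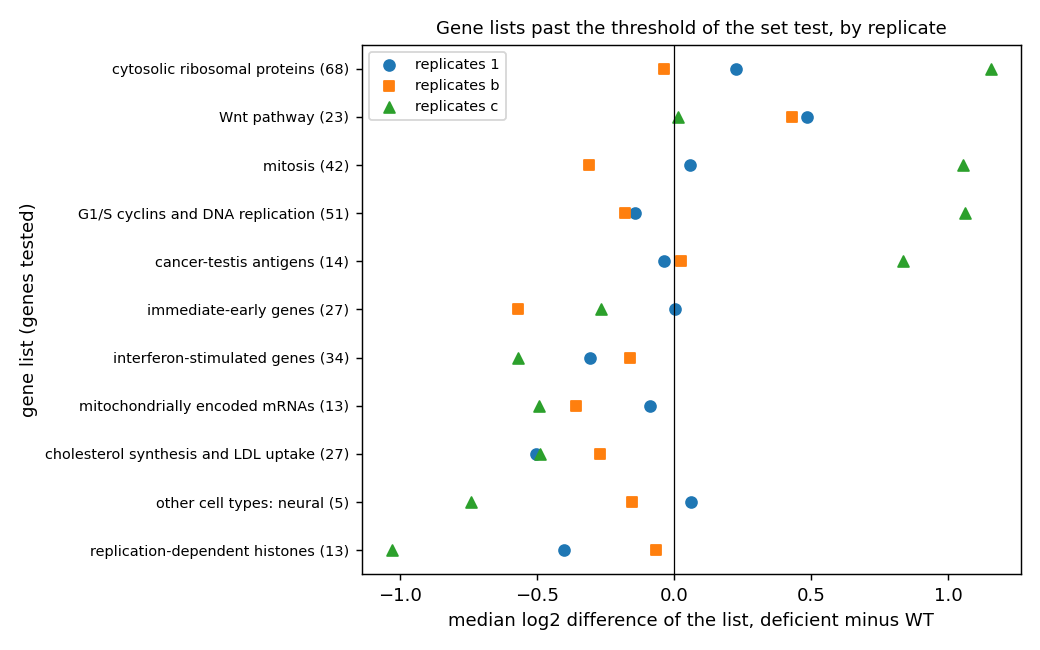
Median log2 difference, clone minus WT, of the 11 gene lists past the threshold of limma's camera, with the number of genes tested in parentheses and a marker for each replicate label. The cholesterol and interferon lists lie below 0 in all 3 pairs, while the ribosomal, mitosis and replication lists lie above 1 in replicate c alone.

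The replicate pairs differed in how far they shared the genotype difference. For replicates b and c the pairing rests on the labels alone, since r within their table was -0.17. Across genes, which are not independent replicates, the differences of replicates 1 and b correlated with r = 0.52, those of 1 and c with 0.24 and those of b and c with 0.17. Genes that differed at least 2-fold in the same direction in all 3 pairs numbered 35 higher and 48 lower, against 5 with replicate c opposite to the others, 3 with replicate b and 3 with replicate 1. At a log2 difference of at least 0.5 these numbers were 234 and 257, against 119, 30 and 31. A genotype effect that differed between the tables was found for 0 genes by limma after adjustment, with 429 at an unadjusted p under 0.05.

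Genes of the distal part of chromosome 14, examined after the values were seen, lay higher in the clone together. A step along the chromosome was placed from the same differences. From VIPAS39 at 77426675 to the last tested gene, the median log2 difference of 112 protein-coding genes, relative to all protein-coding genes, was 0.77, 0.56 and 0.76 for replicates 1, b and c, and 93 were higher in all 3 pairs. The part includes NUDT14, AKT1 and TNFAIP2. The 68 genes between ZFP36L1 and VIPAS39 had medians of -0.07, -0.03 and -0.40, and the 218 genes on the other side of ZFP36L1 had 0.01, 0.02 and -0.09. GTSF1 lay in a part of chromosome 12 from 50 to 60 Mb, where 138 genes had medians of 0.43, 0.29 and 0.32.

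**Figure D3:**
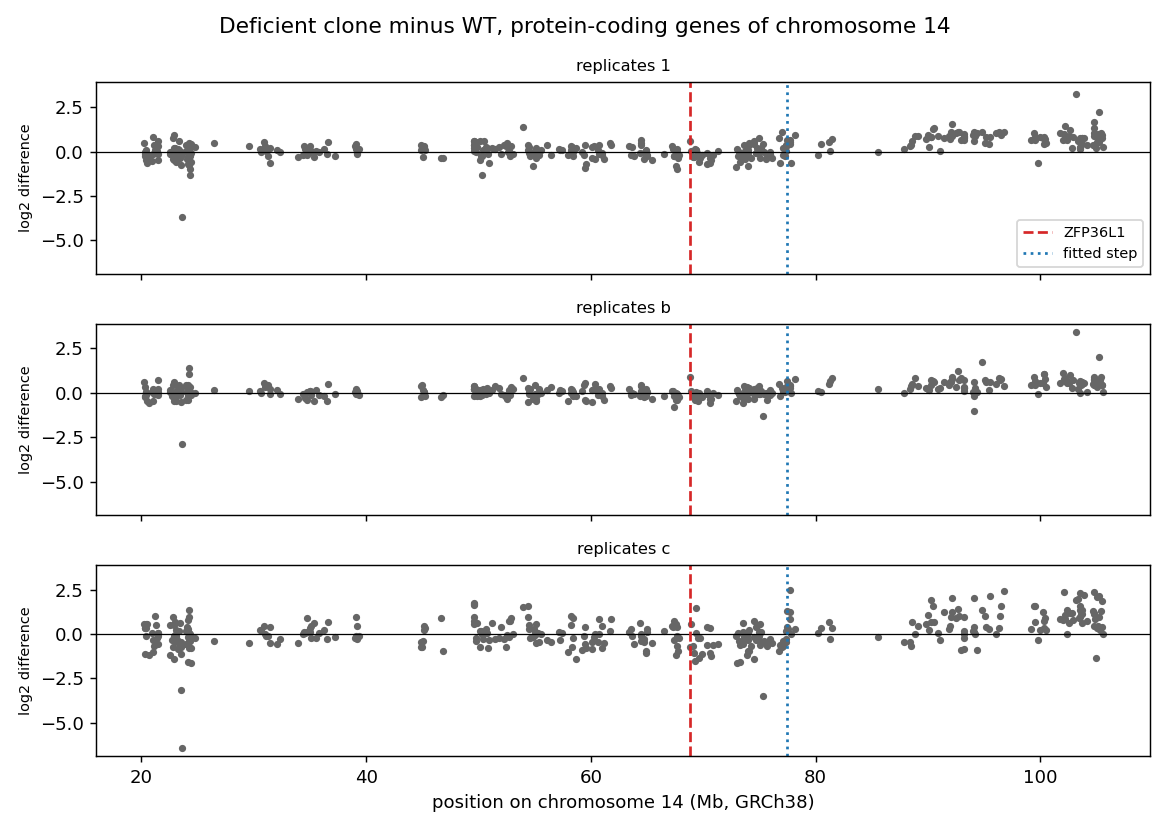
Log2 difference, clone minus WT, of each tested protein-coding gene of chromosome 14 against its position in Mb (GRCh38), relative to the median of all protein-coding genes, with a panel for each replicate label. The dashed line marks ZFP36L1 and the dotted line the step, 8.63 Mb further along, beyond which the medians were 0.77, 0.56 and 0.76.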

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

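The limma-voom fit, the crossed block and the removal of near-0 genes were chosen after the data were seen. The 7 calls depended on the setting. At a mean FPKM of at least 5, the filter itself removed CDA, BCHE, COL22A1 and AC004884.2. KLK6, GTSF1 and NUDT14 still passed there (limma adjusted p between 0.00293 and 0.0403). The cause was otherwise not tested, except where fewer libraries entered. No gene was higher, against 3, without a filter on low values, with the replicate block, without the table term, with the second table alone, with that table and the replicate block, or with limma-voom on its recovered reads, and 5 were with equal medians. Genes called lower, against 4, numbered 1 without a filter, 1 at a mean FPKM of at least 5, 1 with the replicate block, and 0 without the table term, with the second table alone, with that table and the replicate block, or with limma-voom. Unadjusted p under 0.05 held for 1782 genes with the block, 223 without the table term, 1110 and 853 for the second table without and with the block, and 1165 with limma-voom. The crossed block, which pairs WT b with deficient c, gave 3 higher and 5 lower, with 2574 at an unadjusted p under 0.05.

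Leaving out libraries or replicate pairs gave 0 to 448 genes higher and 0 to 457 lower, the most without replicate c. No library or pair left out turned the direction of a called gene, which adds little, since each went the same way in all 3 pairs. KLK6 passed the threshold in 4 of these 9 fits and each other called gene in 3 of 9. Lists past the threshold numbered 8 to 12 in the other settings, against 11, and 0 with an estimated correlation. These were not always the same lists. Of the 11 without replicate c, 5 had passed with it in the same direction, 1 in the other direction and 5 not at all. The ZFP36L1 log2 fold change was -0.03 without WT replicate b, -0.05 without replicate b and -0.073 with limma-voom, against 0.26, and lay between -0.05 and 0.70 over the leave-outs. With a library of replicate 1 left out, the other adds nothing to the genotype estimate, so these fits give the ZFP36L1 value of the second table alone (0.12). With a pseudocount of 0.1, GTSF1 (limma adjusted p = 0.122) and NUDT14 (0.0517) did not pass, and NUDT14 did not pass with quantile normalization (0.0612). Over the settings, adjusted p lay between 7.6e-10 and 1 for GTSF1 and between 5.39e-05 and 1 for NUDT14. The odds ratio of TATTTAT among called genes could not be fitted, since no searched call held it. The depth of the first table is unknown, so the precision of replicate 1 is too.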

Other observations

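Chosen after the result was seen were the tests of growth state, of alternate copies of a locus, of a copy gain on chromosome 14, of the bins of neighbouring genes, and of the label by chromosome segments. The other tests were set before.

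Several genes without a call over all genes went the same way by at least 2-fold in all 3 pairs, and they were picked after their values were seen. THBS1, a secreted matrix protein, had log2 differences of 1.53, 1.47 and 2.70, and TNFAIP2, a target of NF-kB, 3.16, 3.40 and 2.04. The laminin chain LAMB3 had -1.96, -1.95 and -3.33, and TGM2, a transglutaminase, -2.60, -2.00 and -2.73. VWDE and ETV1, close together on chromosome 7, were listed at 0 FPKM in all 3 clone libraries and above 0 in all 3 of WT. Both lie between 10 and 20 Mb, where 13 genes had medians of -0.58, -0.62 and -0.66 relative to all protein-coding genes. Of these genes, 9 were lower in all 3 pairs.

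Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many calls, the real one with 7, and the highest other gave 2. With 10 splits a share under 0.05 cannot be reached.

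With libraries paired by their labels, the genotype difference of replicate c departed from the others. Within the second table r between same-labelled libraries was -0.17, so the values there do not bear out that pairing. GC content was argued against, with a Spearman rho of -0.03 across genes, and gene length stayed open, with -0.15 between the bounds set (0.1 and 0.3). Of 905 genes called from the other pairs, 70.8% went the same way in replicate c, between the bounds of 60% and 80% set beforehand, so those genes left a wrong label open. Chromosome segments picked from the other pairs argued against a library of the other genotype in replicate c. There 19 of 19 went the same way, with a median signed difference of 0.40. An exchange of b and c within a genotype stayed open, since each pair would still set the clone against WT. A different growth or RNA state of the cultures stayed open. Between replicates b and c, 3 of 4 lists shifted by over 0.3 in opposite directions in the genotypes (mitosis -0.64 in WT and 0.73 in the clone), which largely restates their differences in replicate c, and the fourth, mitochondrial mRNAs, shifted the same way in both (0.37 and 0.17).

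Neighbouring genes moved together. Of 289 bins of 10 Mb, 6 were higher and 7 lower by at least 0.3 in all 3 pairs, and 3 of 1000 shuffles of gene positions had any such bin. The higher bins lay on chromosomes 12, 14 and 20 and the lower ones on 2, 5, 7 and 16. From 80 to 90 Mb on chromosome 16, 69 genes had medians of -0.53, -0.42 and -0.40, and 42 were lower in all 3 pairs. The gene lists were not tested without the genes of these bins. No DNA was measured, and the clone and the genotype stay confounded.

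On chromosome 14, the genes directly after the edited ZFP36L1 gene were not higher, which argues against a gain that begins there. The 30 genes that start within 5 Mb after ZFP36L1 had medians of -0.22, -0.18 and -0.32 for replicates 1, b and c. This window lies before the step placed from the same differences, so it restates that step and is no separate test. Where the step itself comes from was not tested.

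In all, 92 protein-coding genes with at least 20 FPKM in both libraries of the first table were listed under 0.1 in every library of the second, among them TUBB, ACTN4 and PRPF8. Of these, 37 lay on chromosome 6 between 28 and 34 Mb, against 16 of 5361 other abundant genes, a ratio of shares of 134.8. Loss of reads that match alternate copies of the locus may account for those. A pseudogene named after the gene was listed for 22 of the 92 and for 1268 of the 5361, a ratio of shares of 1.01, so no excess was seen. Pseudogenes under other names were not searched, which leaves a loss to them open. No biological explanation was tested, since both genotypes were alike.

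Transcripts with TATTTAT may lie slightly higher in the clone. With untranslated region length, A+T share and expression as covariates, the coefficient over 12044 genes was 0.10, 0.09 and 0.06 log2 units for replicates 1, b and c, a mean of 0.083 (SD 0.022 between pairs). Medians without covariates went the other way in replicate c, at 0.08 with the element and 0.13 without. None of the 6 called genes with a searched 3′ untranslated region held it, and with 1 clone the genotype is not separated from the clone.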
